A study of Homo sapiens with 4 samples.

How the data were processed

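Total RNA was taken from SK-HEP-1 cells with a control or an IL-37 lentivirus, 2 arrays per group, and hybridised to a 1-colour Agilent expression array. Per the labels' protocols, 100000 cells were plated for 24 hours in medium with 10% serum, and 0.5 ug of RNA was amplified and labelled with Cy3. The scanner output was deposited as intensity per spot from Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The processed signal is a background-corrected intensity, per the file headers, and comes with flags for spots well above background, saturated or non-uniform. The deposited series table holds log2 values of the same arrays. Their differences between arrays were set against those of the log2 processed signal, with a constant per array left free. The comparison therefore does not show how the arrays were scaled. The values are centred per probe on a baseline that stays unknown, since only 4.0% of probes have a median within 0.01 of 0 over these 4 arrays. The table's column medians are -0.122, -0.088, -0.010 and 0.108 for control 1, control 2, IL-37 1 and IL-37 2. Its direction is that of the scanner signal. Feature numbers match in 54.6% of its 58201 values within 0.03 log2. In 2 stretches with 26947 probes (46.3%), each value belongs to the next feature number, and after realignment 99.5% match. The table was used only as an alternative, and no value column of another series was present.

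The main values are log2 of the processed signal minus each array's 75th percentile. Control spots and non-uniform spots (6, 5, 13 and 106 on the 4 arrays) were left out, and spots of 1 probe were averaged. A probe was tested if well above background on both arrays of at least 1 group. Accessions on the array were named without version through a RefSeq table of assembly GRCh38.p14. This gave a symbol to 31100 of 58201 probes (53.4%), 22435 symbols in all, of which 6754 had more than 1 probe, and the other 27101 probes kept the file's name. The array's own annotation is of an older build, so no positions are printed. For each gene the probe with the highest mean over the 4 arrays was used. Of called genes with a symbol, 1911 had more than 1 probe tested, and 377 of these had a probe of opposite sign.

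Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg at 0.05) over 28787 features, with no covariate. The prior carried 1.84 degrees of freedom, and the median SE was 0.076 log2. Where every array of a group was not well above background, the fold is a bound. It sets the bright group's mean against, per array of the dim group, the higher of the probe's own signal and the lowest signal well above background, and 437 called features are of this kind. The procedure was tested on simulated data with 50 features changed at each of 4 sizes among 28787. At 0.5, 1, 2 and 4 log2 it recovered 0%, 30%, 86% and 88%, with 6 false calls among 108. Recovery of small changes is lower there than with many true changes, since the adjusted threshold is stricter.

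A set of 39 gene lists was tested with camera at a preset correlation of 0.01, and again with an estimated correlation, fry and a rank-based set test. The lists, the groups, the tests, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule takes IL37, the 12 largest rises and 12 largest falls among called features with a gene symbol, up to 4 members per described list by size with called members first, and 13 reference genes. Some genes that the rule takes are not reported here. The other settings were normexp background correction with an offset of 50, quantile normalization, centring on the median, the authors' table, other filters, each probe on its own, other variance models, the replicate number as a block and leaving out each array. The files hold no mean signal column, so normexp used the median signal and the median local background. A slide block was not run because all arrays share 1 slide. Spike-in scaling, tested symbols only and the authors' table under its own feature numbers were added after seeing the data. Signal above background sets the depth: differences of probes near background are bounds or carry larger errors. Random gene sets were drawn 10000 times from 20 bins of mean signal with numpy 2.4.6.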

Results

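Gene expression was measured by 1-colour microarray in SK-HEP-1 cells, a human line from a liver adenocarcinoma that the labels describe as hepatocellular carcinoma and that is known to carry endothelial features. One set of cells had received an empty control lentivirus and the other a lentivirus encoding IL-37, an IL-1 family cytokine known to dampen inflammation through IL-18 receptor alpha and SIGIRR. The comparison asks what IL-37 does to the transcriptome of this line. Each group had 2 arrays, all 4 on 1 slide and from 1 scan, and their number limits the precision. Between 57.7% and 61.5% of 58201 probes were well above background on each array, and no probe was saturated. The 75th percentile of signal was 701.5 and 728.2 on the control arrays against 564.0 and 512.4 on the IL-37 arrays. Spike-in transcripts lay 0.05 and 0.17 log2 above their mean over the 4 arrays on the control arrays, and at -0.06 and -0.16 on the IL-37 arrays. Replicates correlated at Pearson r = 0.998 (control) and 0.995 (IL-37) across probes, and arrays of different groups at 0.984 to 0.986. These correlations run across probes, which are not independent replicates.

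The IL37 transcript was 18.9-fold higher in the cells with the IL-37 virus. Its level relative to each array's 75th percentile was -2.21 ± 0.03 log2 in control (SD, n = 2) and 2.03 ± 0.12 in IL-37 (SD, n = 2). The difference was 4.24 log2 with an SE of 0.08 (limma adjusted p = 0.00145). The probe was also well above background on both control arrays, so the control level was measured and not bounded. Of its receptor chains, SIGIRR was 1.59-fold higher (limma adjusted p = 0.0167), while IL18R1 was not well above background on both arrays of either group and was not tested.

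In cells with the IL-37 virus, 48 of 49 G2/M genes, 41 of 43 G1/S genes and 21 of 25 cholesterol synthesis genes fell, while 22 of 30 hypoxia targets, 12 of 23 glycolysis genes and 20 of 41 interferon-stimulated genes rose. These lists passed camera at its preset correlation, and none of them with an estimated correlation (adjusted p = 0.294 for the first 3 and for hypoxia, 0.623 for glycolysis and 0.473 for interferon). With an estimated correlation, camera rests on the residual degrees of freedom of only 4 arrays, so lists could hardly pass it. IL1A and IL1B rose and IL6 fell. Of 28787 features tested, 4945 were higher and 4784 lower in IL-37 (limma, adjusted p under 0.05), and 13643 had an unadjusted p under 0.05. A log2 difference of at least 1 was reached by 732 of the higher and 408 of the lower features. With 2 against 2 arrays, group values did not overlap for 72.3% of features, where chance gives 33.3%. The count rests on both control arrays: without control replicate 1 it was 415 in total, and without control replicate 2 it was 405, and 125 and 126 of 167 named genes called then lost the call. Without IL-37 replicate 1 it was 6110, and without IL-37 replicate 2 it was 6184. The main fit pools the spreads of the 2 groups, which were unequal. The median absolute difference was 0.074 log2 between the control arrays and 0.101 between the IL-37 arrays. Leaving out a control array leaves the wider IL-37 pair to set the error. The share of calls that were higher, 50.8%, was 32.1% after centring on the median and 22.1% after spike-in scaling. These 2 settings moved the median of all features from 0.01 to -0.10 and -0.18 log2 respectively.

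IL13RA2, a decoy receptor for IL-13, was at least 34.8-fold higher in IL-37 and not well above background in control. CCKBR, a gastrin receptor, was at least 15.2-fold higher and PLA2G2F, a secreted phospholipase, at least 19.8-fold. KYNU, which encodes kynureninase of tryptophan breakdown, rose 21.8-fold, and CCDC8 rose 35.9-fold, both measured above background in each group. TMEM71 rose 30.9-fold by its brighter probe, while its second probe differed by -0.96 log2. GUCY2EP (at least 6.89-fold), EFS (at least 7.04-fold), MARCHF1 (at least 4.97-fold), GPC6 (at least 3.58-fold) and PTGS1 (at least 3.64-fold) were not well above background in control. Limma adjusted p for these genes lay between 0.00103 for MARCHF1 and 0.0064 for PLA2G2F.

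PIK3CG, the gamma catalytic subunit of PI3-kinase, was at least 7.99-fold lower in IL-37. TCF4, a basic helix-loop-helix factor, was at least 4.70-fold lower and SSTR2, a somatostatin receptor, at least 11.6-fold lower. NPW, a neuropeptide, and GPX7, an endoplasmic reticulum peroxidase, were measured in both groups and were 12.8-fold and 10.0-fold lower. BRDTP1 (at least 3.83-fold), MYRIP (at least 4.33-fold), HS6ST2 (at least 3.10-fold), SLC43A2 (at least 4.76-fold) and FAM221A (at least 2.83-fold) were not well above background in IL-37. Limma adjusted p for these genes lay between 0.00142 for PIK3CG and 0.00998 for SLC43A2.

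**Figure D1:**
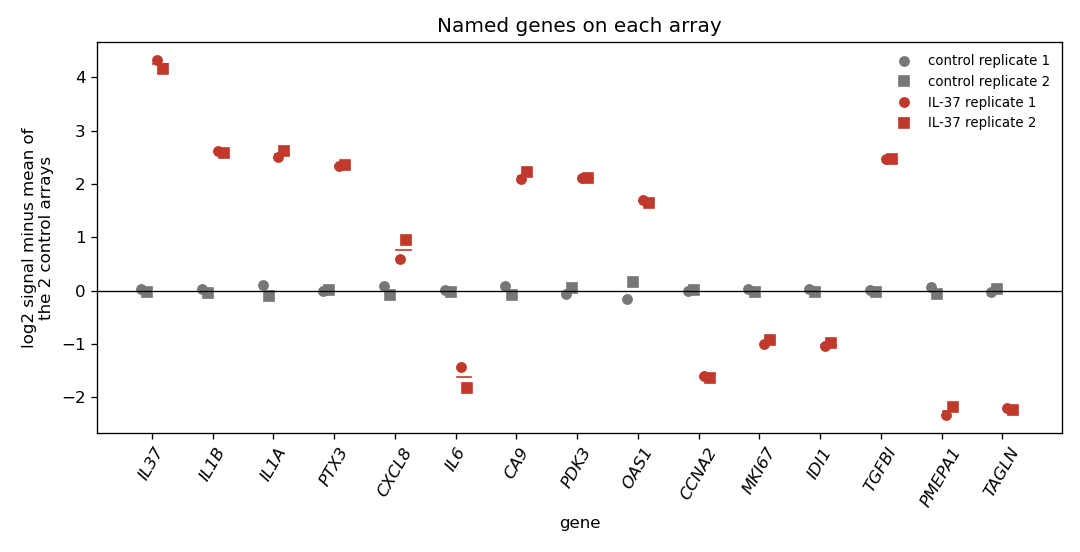
Signal of 15 named genes on each array, as log2 signal minus the mean of the 2 control arrays (vertical axis) for each gene (horizontal axis). Grey symbols are control arrays, red symbols IL-37 arrays, circles replicate 1, squares replicate 2, and short red lines the mean of the IL-37 arrays. IL37 lies 4.24 above the control mean and IL1B 2.60 above, while IL6 lies at -1.63 and PMEPA1 at -2.26.

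Cell cycle genes were lower as a group. Of 49 measured G2/M and mitotic genes, 48 fell and 1 did not pass the test, with a list median of -0.82 log2. Of 43 measured G1/S and DNA replication genes, 41 fell and 2 did not pass, with a median of -0.79. CCNA2, the cyclin of S phase and mitotic entry, fell by 1.62 log2 (SE 0.05, limma adjusted p = 0.00314). MKI67, a marker of cycling cells, AURKA, a mitotic kinase, and SPC25, a kinetochore subunit, differed by -0.96, -1.09 and -1.19. CLSPN, E2F2, CCNE2 and MCM10, which act in replication or its control, differed by -1.40, -1.32, -1.27 and -1.21. CDK1 differed by -1.10 (SE 0.23), a call that ended under quantile normalization. Of 30 replication-dependent histone genes, 19 fell and 11 did not pass, with a median of -0.46, and H3C7, H4C4, H3C2 and H3C10 differed by -0.95, -0.93, -0.91 and -0.91. Camera's adjusted p was 3.4e-21 for G2/M, 5.66e-18 for G1/S and 1.78e-07 for histones, each 0.294 as an adjusted p with an estimated correlation. Adjusted over the list alone, 49, 43 and 22 members of these lists were lower.

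Cholesterol synthesis genes were lower too. Of 25 members, 21 fell, none rose and 4 did not pass, with a median of -0.64 log2 (camera adjusted p = 1.26e-09, and adjusted p = 0.294 with an estimated correlation). ACAT2, IDI1 and DHCR7, enzymes of the pathway, fell, at -1.12, -1.01 and -0.98 log2. Adjusted over the list alone, 21 members were lower. In the fatty acid list, 3 of 27 members rose and 6 fell (camera adjusted p = 0.589). The desaturases FADS2 and FADS1 fell, at -1.38 and -0.70, while DGAT2 and ACACB rose by 0.78 and 0.60.

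Hypoxia and HIF target genes were higher. Of 30 members, 22 rose, 1 fell and 7 did not pass, with a median of 0.76 log2 (camera adjusted p = 2.08e-09, and adjusted p = 0.294 with an estimated correlation). CA9, a carbonic anhydrase, rose by 2.16 log2 (SE 0.09, limma adjusted p = 0.00407). The pyruvate dehydrogenase kinases PDK3 and PDK1 rose by 2.11 and 1.47, and PFKFB4, a regulator of glycolytic flux, by 1.53. Of 23 glycolysis genes, 12 rose, none fell and 11 did not pass, with a median of 0.31 (camera adjusted p = 0.000185, and adjusted p = 0.623 with an estimated correlation). ENO2 and SLC2A3, a neuronal enolase and a glucose transporter, rose by 1.69 and 1.05, and GAPDH by 0.51 (limma adjusted p = 0.0138). PDK1, PFKFB4 and SLC2A3 are among the genes that belong to both lists, so the list results are not independent. Adjusted over the list alone, 23 hypoxia and 14 glycolysis genes were higher, and 1 of each was lower. Of 45 oxidative phosphorylation genes, 1 rose, 7 fell and 37 did not pass (camera adjusted p = 0.39), with CYCS at -0.78.

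Interferon-stimulated genes were higher on balance. Of 41 members, 20 rose, 4 fell and 17 did not pass, with a median of 0.23 log2 (camera adjusted p = 0.000285, and adjusted p = 0.473 with an estimated correlation). OAS1, an antiviral RNA sensor, rose by 1.68 log2 (SE 0.13, limma adjusted p = 0.00675), the chemokine CXCL10 by 1.37, GBP2 by 1.01 and OASL by 0.98. Adjusted over the list alone, 22 were higher and 4 lower. In the list of MHC class I antigen presentation, 8 of 22 members rose and 2 fell (camera adjusted p = 0.163). HLA-F and HLA-B each rose by 0.71 log2 and HLA-G by 0.62. The HLA transcripts are near-identical in sequence, and the probes need not tell them apart.

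Of 20 measured IL-1 family ligands, receptors and adaptors, 7 rose, 2 fell and 11 did not pass (camera adjusted p = 0.0932). IL1B rose 6.06-fold (2.60 log2, SE 0.06, limma adjusted p = 0.00217), IL1A 5.91-fold and IL18 1.59-fold. Of 30 NF-kB target genes, 10 rose, 7 fell and 13 did not pass (camera adjusted p = 0.317). PTX3, a soluble pattern recognition protein, rose 5.08-fold and the monocyte attractant CCL2 2.51-fold. IL6 was 3.09-fold lower (-1.63 log2, SE 0.15, limma adjusted p = 0.00829), and CXCL8 was 1.70-fold higher (limma adjusted p = 0.0306), a call that ended under quantile normalization. In the IL-6, JAK and STAT3 list, 8 of 28 members rose and 5 fell (camera adjusted p = 0.343). PIM1 and LIFR rose by 0.91 and 0.64 log2 and OSMR by 1.22, with the second OSMR probe at 0.18. STAT3 differed by -0.08 (limma adjusted p = 0.354). Of 21 measured macrophage attractants and checkpoint ligands, 2 rose and 5 fell (camera adjusted p = 0.688), among them CD274, which encodes PD-L1, at -0.92, with its second probe at -0.15, and RAET1E at -0.86.

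Of 35 TGF-beta and SMAD target genes, 17 fell, 4 rose and 14 did not pass, with a median of -0.25 log2. Whether the list passed turned on the setting: camera missed the threshold (adjusted p = 0.0502, and adjusted p = 0.733 with an estimated correlation) but called the list in 7 of 16 other settings, and a rank-based set test gave an adjusted p of 0.0222. PMEPA1, a feedback inhibitor of the pathway, fell by 2.26 log2 (SE 0.09, limma adjusted p = 0.00374) and TAGLN, a smooth muscle actin-binding protein, fell by 2.23. POSTN was at least 4.08-fold lower and TGFBI rose by 2.47. SMAD3 differed by 0.20 (limma adjusted p = 0.121). Among 26 mesenchymal genes, 7 rose and 6 fell (camera adjusted p = 0.991). WNT5A, FN1 and MMP2 fell, at -1.94, -1.59 and -1.51, while VIM was 0.32 higher (limma adjusted p = 0.0265) and -0.04 under quantile normalization. Among 23 epithelial genes, 5 rose and 4 fell (camera adjusted p = 0.991). SPINT2 rose by 1.68, CLDN3 and MARVELD2 fell, at -1.41 and -1.25, DSP was at least 1.64-fold higher, and CDH1 was not well above background on both arrays of either group. Among 37 matrix genes, 12 rose and 11 fell (camera adjusted p = 0.991), with LUM at -2.03, COL5A2 at -1.40 and FBLN2 at least 2.47-fold higher.

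**Figure D2:**
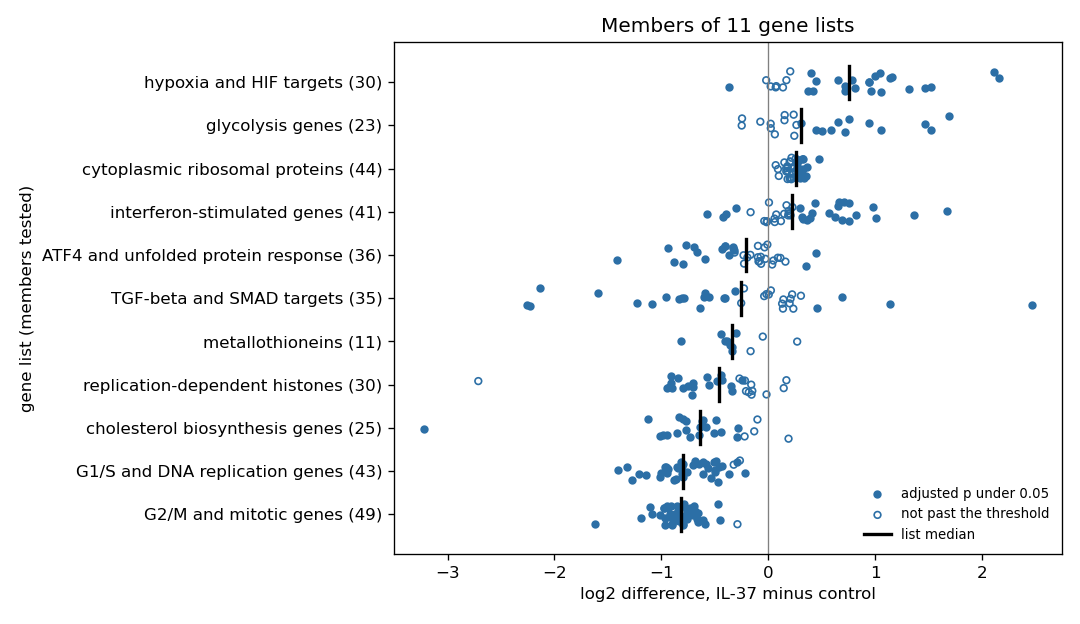
Difference between IL-37 and control on the log2 scale (horizontal axis) for each tested member of 11 gene lists (vertical axis, number of members tested in brackets). Filled points passed a limma adjusted p of 0.05, open points did not, and black bars are list medians. The G2/M median lies at -0.82 and that of hypoxia targets at 0.76, and the TGF-beta list spans 0.

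Stress-related lists were lower or mixed. Of 36 genes of the ATF4 and unfolded protein response, 14 fell, 2 rose and 20 did not pass, with a median of -0.21 log2 (camera adjusted p = 0.000749, and adjusted p = 0.663 with an estimated correlation). CHAC1, SLC7A5, DNAJC3 and SLC3A2 fell, at -1.41, -0.94, -0.89 and -0.80. CHAC1 degrades glutathione, SLC7A5 and SLC3A2 form an amino acid transporter, and DNAJC3 is a chaperone partner. Of 11 genes in the metallothionein list, 8 fell and 3 did not pass, with a median of -0.34 (camera adjusted p = 0.0049, and adjusted p = 0.473 with an estimated correlation). The zinc exporter SLC30A1 fell by 0.82, MT1A, MT1M and MT1F lay at -0.44, -0.40 and -0.39, and the MT1 transcripts are close paralogs. Adjusted over the list alone, 15 genes of the first list were lower and 2 higher, and of the second 8 were lower and 1 higher. Among 19 heat shock genes 3 rose and 6 fell (camera adjusted p = 0.355), with HSPB8 at 0.80 and DNAJB1 at -0.62. Among 26 NRF2 targets 6 rose and 4 fell (camera adjusted p = 0.653), with AKR1C1 at 1.17 and HMOX1 at -0.80. Among 32 p53 targets 3 rose and 9 fell (camera adjusted p = 0.151), with TP53I3 at -1.28 and FAS at -0.70.

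Of 44 cytoplasmic ribosomal protein genes, 19 were higher, none lower and 25 did not pass, with a median of 0.26 log2 (camera adjusted p = 1.61e-07, and adjusted p = 0.867 with an estimated correlation). Under quantile normalization the median was 0.03 and the call ended (camera adjusted p = 0.442), and the median was 0.075 with spike-in scaling and 0.15 with centring on the median. RPLP2, RPL19 and RPL3 lay at 0.47, 0.36 and 0.36. Adjusted over the list alone, 28 were higher. ACTB, another abundant transcript, differed by 0.06 (limma adjusted p = 0.463).

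The other lists did not pass camera in the main setting. Among lists given above, oxidative phosphorylation and p53 were each called in 3 of 16 other settings, heat shock in 2 and MHC class I in 1. Of those that follow, the cyclin and apoptosis lists were each called in 2 of 16 other settings, and the rest in none. Among 16 cyclins, CDKs and inhibitors 1 rose and 5 fell (adjusted p = 0.163), with the CDK inhibitor CDKN1C at 1.23, CDKN2C at -0.97 and CDKN1A at 0.13 (limma adjusted p = 0.151). Among 38 apoptosis regulators 7 rose and 12 fell (adjusted p = 0.499), with BNIP3 at 1.05 and BIRC5 at -0.90. Autophagy genes had 7 higher and 5 lower of 39 (adjusted p = 0.589), and lysosomal genes 10 higher and 3 lower of 36 (adjusted p = 0.589), with CTSB at 0.89. Among 35 genes of the PI3K, AKT and mTOR pathway 8 rose and 8 fell (adjusted p = 0.876), with FOXO1 at 1.01 and PIK3R3 at -1.11. Immediate early genes had 6 higher and 8 lower of 28 (adjusted p = 0.542), with EGR1 at -1.56 and FOS at -0.94. YAP and TAZ targets had 5 higher and 6 lower of 24 (adjusted p = 0.778), with CCN2 at -0.96 and CCN1 at 0.52. Wnt targets had 5 higher and 3 lower of 16 (adjusted p = 0.39), with LEF1 at -2.56 and NKD2 at 1.52. Notch targets had 4 higher and 2 lower of 12 (adjusted p = 0.862), with NOTCH3 at 1.34 and NOTCH4 at -0.84. Angiogenic factors had 3 higher and 7 lower of 25 (adjusted p = 0.991), with ANGPT1 at 2.40 and THBS1 at -0.83.

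No list of cell type markers passed camera in the main setting, but the hepatocyte list was called in 3 of 16 other settings. Hepatocyte markers had 4 higher and none lower of 17 measured (camera adjusted p = 0.0942), with SERPINA1 at 0.90 log2 and CYP2E1 at least 2.03-fold higher, while ALB was not well above background on both arrays of either group. Endothelial markers had 3 higher and 3 lower of 16 (adjusted p = 0.991), with FLI1 at 0.61 and LMO2 at least 2.06-fold lower, and PECAM1 was likewise not tested. Stellate cell and fibroblast markers had 4 higher and 6 lower of 14 (adjusted p = 0.711), with COL1A1 at -0.79. Leukocyte markers had 5 higher and none lower of 21 (adjusted p = 0.377), with LST1 at 0.76. Biliary and progenitor markers had 3 higher and 4 lower of 18 (adjusted p = 0.711), with SPP1 at 1.42. With an estimated correlation 0 of 39 lists passed camera, at adjusted p from 0.294 upward, and 5 had an unadjusted p under 0.05. That version rests on the residual degrees of freedom of only 4 arrays, so failure alone does not show that correlated members made the calls. For cholesterol genes the estimated correlation was -0.01, below the preset 0.01, yet camera's unadjusted p went from 9.71e-11 to 0.0187. The estimate was -0.019 for hypoxia, -0.031 for histone and 0.01 for metallothionein genes. Above the preset lay interferon-stimulated (0.03), G1/S (0.085), G2/M (0.099), ATF4 (0.148), glycolysis (0.205) and ribosomal protein genes (0.727). For those lists, and most for the ribosomal one, correlated members may account for part of the strength of the call. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Control arrays lay in one slide column and IL-37 arrays in another, so slide column and group cannot be told apart.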

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

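Spike-in scaling, symbols only and the authors' table under its own feature numbers were chosen after the data were seen. The IL37 level kept its direction and its call in every setting that read its own probe, at 3.71 log2 with normexp. The authors' table under its own feature numbers gave 1.09, but that value belongs to another probe and does not bear on IL37. The count of higher features was 10162 with normexp (62.2% of calls) and 12371 with no filter on dim probes (75.2%). These settings and spike-in scaling moved the median of all features to 0.10, 0.14 and -0.18 log2. Spike-in scaling gave 2619 higher and 9248 lower, and centring on the median 3321 higher and 7035 lower. At an adjusted p of 0.01 there were 1234 higher and 1061 lower, and at an absolute log2 difference of 1 there were 732 and 408. With 1 array left out, higher features ranged from 298 to 3117 and lower features from 107 to 3199. The lone array is then assumed to vary like the other group, and the lowest values come from leaving out either control array. Of 39 lists, camera called 10, camera with an estimated correlation 0 (5 at an unadjusted p under 0.05), fry, which tests a list against no change, 19, a rank-based set test 11, and camera 17 with normexp and 17 with no filter. Of 167 named genes called, 24 lost the call in at least 1 setting that used all arrays, 125 and 126 without control replicate 1 or 2, and 22 and 26 without IL-37 replicate 1 or 2. VIM reversed to -0.041 under quantile normalization. The cause was not tested. Replicate numbers need not pair these arrays: deviations of the 2 arrays with number 1 from their group means correlated at 0.076. Arrays with number 2 mirror these deviations and give no further value. With the replicate number as a block, 3782 features were higher and 3447 lower, and 10 lists were called. Signal over background limits dim probes, of which 437 called features have only a bound.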

Other observations

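The tests of slide position and of chromosome copies were chosen after the result was seen. Features without a gene symbol split unevenly: of 11767 tested, 1951 were higher and 1155 lower in IL-37. This split was not checked in other settings. Over all features the higher share of calls turned on scaling and filter: 50.8% here, 75.2% with no filter on dim probes and 22.1% with spike-in scaling. Some large differences lay outside the genes named by rule, and the following were picked after their values were seen. The UDP-glucuronosyltransferases UGT2B7, UGT2B10 and UGT2B11 were 3.12, 3.06 and 3.06 log2 higher, but they are close paralogs whose probes need not tell them apart. The non-coding transcript MIR210HG, host of a hypoxia-responsive microRNA, was 2.36 higher. The MAGE family genes MAGEC2 and MAGEA6 differed by 2.87 and -2.04. PPARG, a nuclear receptor of fat cell differentiation, was at -2.50 and IGFBP2 at -2.75.

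Cell cycle lists were lower and hypoxia and glycolysis lists higher while the IL-37 arrays were dimmer overall. A bias that depends on brightness was set against 10000 random lists of like mean signal, whose median was -0.087 log2 for G2/M genes and whose lowest was -0.295, against -0.818 observed. For hypoxia targets and glycolysis genes the highest matched lists reached 0.243 and 0.293, against 0.756 and 0.310, so glycolysis cleared them only narrowly. Ribosomal protein genes cleared them too (0.263 against 0.217), yet their median was 0.028 under quantile normalization. Clearing matched lists thus does not by itself exclude brightness, but the G2/M, hypoxia and glycolysis lists kept their camera calls there. The values argue against brightness as the whole source for G2/M and hypoxia genes, less firmly for glycolysis genes. Matched lists reached the medians of 3 lists, so the test does not settle these: ATF4 genes (-0.210 against a matched median of -0.079, 478 of 10000 as far from it), metallothioneins (-0.337 against -0.008, 62) and interferon-stimulated genes (0.228 against -0.004, 12). Position on the slide stays open, since 0 slide columns hold arrays of both groups. It cannot be told apart from IL-37 or from any other difference between the 2 groups of cells.

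Genes of 1 chromosome, the one that carries HIF1A, FOS and DICER1 in the RefSeq table, were lower together in IL-37. Their median was -0.182 log2 over 461 genes (-0.193 and -0.155 on the 2 IL-37 arrays), against -0.038 over 14016 autosomal genes, and 37.3% were called lower against 22.9%. None of 10000 gene sets of like signal lay as far out (median -0.031, lowest -0.107). Clearing matched sets does not by itself exclude brightness, and the chromosome medians were not computed under quantile normalization, so brightness stays open here. The permutation p was 0.0001, the smallest they can give (adjusted p = 0.0011 over 22 chromosomes), and genes are not independent replicates. Without members of the 39 lists, 438 genes were left, with a median of -0.187. Too few genes were removed to move the median far, so this does not bear on these lists as the source. All 8 equal stretches along it had a median below that of all genes, but 9025 of 10000 shuffled orders of its genes gave this too. The test thus does not bear on a copy number that differs between the 2 groups of cells. That hypothesis stays open, and a copy number or SNP array of both groups would test it. The chromosome with SMAD3 and B2M had a median of -0.126 (adjusted p = 0.0011), and the one with EP300 lay the other way, with a median of 0.036 (adjusted p = 0.0411).

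Probes that were well above background on both arrays of 1 group and neither of the other numbered 1263, with 1058 in control only and 205 in IL-37 only. The 2 other ways to pair the arrays gave 223 and 220, so noise of dim probes may account for part of the pattern, and its share stays open. The dimmer IL-37 arrays favour the first direction. Many cells of another type in 1 group could switch their markers, but no list of 5 cell types had more than 2 members that switched in 1 direction, CD34 and LMO2 among 35 endothelial markers (5.7% in control only, against 1.4% of all symbols). The leukocyte and biliary lists had 3.6% and 4.8% in control only. In IL-37 only, hepatocyte and biliary lists had 2.6% and 4.8% against 0.4% of all symbols. Each of these 4 shares is 1 marker. A small admixture need not carry markers across the background threshold, so the test cannot exclude it. Since the line itself is known to carry endothelial features, switched endothelial markers need not mark other cells. Whether genes such as IL13RA2 and PIK3CG switched through IL-37 or through divergence of the transduced cells was not tested. The labels do not say that either virus was given to more than 1 population.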
